A study of Homo sapiens with 12 samples.

How the data were processed

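RNA from HGC27 cells with FTO knockdown and from control cells was fragmented and, in part, enriched with an m6A antibody, per the labels' protocols. Each condition had 3 IP and 3 input libraries, 12 libraries in all, sequenced as paired ends. The labels do not say whether libraries numbered 1 to 3 came from separate cultures or, for the knockdown, from different short hairpin RNAs, so p-values measure only the spread between these samples, which may be technical. The protocol calls the treated cells a knockdown and the genotype label calls them a knockout; they are called knockdown here, since FTO RNA remained at a mean of 0.793 FPKM. Samples were grouped by their titles, and the tests, gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where a choice is said to have been added later.

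Bowtie 0.12.2, HISAT2 2.0 and StringTie 1.3.0 are named per the submitters' processing notes, without their roles. The peak caller and its settings are not given in the sources used here. Those notes also name the genome build mm8, a mouse build, but gene identifiers and positions were human. Of 18054 transcripts that matched a gene of the RefSeq table for GRCh38.p14 by symbol, 99.4% had positions overlapping the span of that gene, so positions are given as in the files and read as GRCh38. Positions are counted from 1.

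Per the file headers, expression came as FPKM per input library, computed by the authors, with no further scaling stated. These FPKM values were listed for genes with a differential m6A peak, so expression was tested in a selected part of the transcriptome. Per the file headers, the differential peak table gave a log2 fold change of m6A, a p-value and a score, the log10 of the adjusted p. The deposited log2 values of both m6A and expression were control over knockdown. For expression this was seen by recomputing them, to within 1.5e-13. For m6A, the deposited value had a rho of -0.813 with the log2 ratio of knockdown over control enrichment over 3898 peaks. Both were therefore turned to knockdown over control. Per the file headers, each peak list gave the ratio of IP over input (fold enrichment) and, as scores, the log10 of the p-value and of the adjusted p-value. Each condition had a single deposited list, so replicates had been pooled or merged before deposition. The largest p in either list was 0.0501, and the largest p of the differential peaks used was 0.049, so the files hold peaks past a threshold near 0.05.

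From these values the following was computed. FPKM were taken as log2(FPKM + 1), so fold changes on that scale understate the change of low genes, and genes with a mean of at least 1 FPKM over the 6 input libraries were tested with limma 3.58.1 (empirical Bayes with a trend, two-sided, no block) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Low FPKM values showed no steps of whole reads (smallest value above 0, 7.49e-07), so depth was unknown and no count test was run. On simulated data built on the 4515 tested genes, the test recovered 40.3%, 95.5% and 97% of genes changed by 0.2, 0.5 and 1 on the log2 scale, and 16 of its 171 calls were unchanged genes. No library pair held identical values. Gene lists were tested with camera at a preset inter-gene correlation of 0.01 and with an estimated one, adjusted over 23 lists with a measured member. Fry was planned beside camera. It asks whether the members of a list changed, not whether they changed more than other genes.

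The 24 lists included FTO and the study's named genes, m6A writers, erasers and readers, ferroptosis suppressors, ferroptosis drivers and markers, HOX cluster genes, G2/M and G1/S cell cycle genes, apoptosis regulators, epithelial-mesenchymal genes, the unfolded protein response with ATF4 targets, cholesterol synthesis, interferon-stimulated genes, NF-kB targets, the hypoxia response, oxidative phosphorylation, ribosomal proteins, mitochondrially encoded transcripts, histones, immediate early genes, transcripts linked to FTO in published work, and gastric epithelial, fibroblast and immune markers. Named genes were FTO, HOXC8 and MDM2, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, and the 2 members of each list with the smallest p. Named peaks were the 10 largest rises and falls (1 per gene, at least 1 FPKM), every differential peak of the study's genes, and the 2 members per list with the smallest peak p. For FTO, HOXC8, MDM2, MYC, MALAT1 and NEAT1 the peak of highest enrichment in each condition was also taken. Some genes that these rules would name, and a list tied to 1 of them, are not reported here. Further list members are named as examples of their list.

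Peaks of both lists were compared with bedtools 2.31.1 on their exonic blocks; an overlap of at least 1 bp counted, except where the strands of both gene models were known and differed. Strand was known for 90.2% of control and 90.7% of knockdown peaks. The knockdown list repeated 3 peaks, which were counted once. The gene named for a peak differed from the gene model on which it was called in 22.6% of control and 21.7% of knockdown peaks. Regions are those of the deposited annotation, and shares around the stop codon were not computed. Each peak had a single label, with no class for coding sequence, so a label may not cover the whole peak. The peak of TGFB2 labelled 5' UTR, for example, spanned 59026 bp. Intervals for shares are exact binomial intervals at 95%. Of the 8970 differential peaks listed, 283 without a gene name held values above 1 where a p-value belongs and were left out, leaving 8687. The differential peak calls are the authors', and they were described, not refitted. Lists among differential peaks were tested by Fisher's exact test (two-sided, SciPy 1.17.1) against the 19340 genes with a peak in either list or a differential peak, over 48 tests of 24 lists and both directions. The relation of m6A to expression used the peak of largest absolute change per gene, Spearman's rho and 100000 permutations. The number of neighbouring genes was that of RefSeq protein-coding genes within 500 kb. Gene Ontology terms with 10 to 500 genes in the background were tested by Fisher's exact test.

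Alternatives covered the pseudocount, the filter on FPKM, quantile normalization, median-centring, limma without a trend, the authors' q-values, a replicate block, leaving out each input library, thresholds on peaks, the overlap rule and the background of list tests. Tests of single IP libraries and of sequence motifs were not run, since neither values of IP libraries nor a genome sequence were used here.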

Results

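FTO is an enzyme that removes the methyl group from N6-methyladenosine (m6A), a modification of adenosine found within messenger RNA and long non-coding RNA. The series asks how FTO restrains ferroptosis, an iron-dependent form of cell death, by way of HOXC8 and MDM2. The cells were HGC27, an established human gastric carcinoma line, with FTO knocked down or as controls. Titles of the control samples read WT and Con and name no control hairpin. RNA fragments bound by an m6A antibody were sequenced as IP libraries, and the fragments before enrichment as input libraries, with 3 of each kind per condition and 12 libraries in all. Values per library were used for the 6 input libraries, as FPKM of 6396 genes. All of these genes had a differential m6A peak in the authors' deposited table, so the counts of genes below describe that selected part of the transcriptome. FPKM summed over these genes to 74330, 74289 and 78461 in the control libraries and to 86902, 83712 and 84326 in the knockdown libraries. Sequencing depth was unknown. Input libraries of the same condition had Pearson correlations of 0.9877 to 0.9923 on the log2 scale, against 0.9583 to 0.9689 between conditions.

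FTO RNA was 7.00-fold lower in the knockdown libraries. It stood at 5.48, 5.68 and 5.52 FPKM in the controls and at 0.786, 0.83 and 0.765 FPKM after knockdown. With limma and Benjamini-Hochberg adjustment, FTO fell by 1.87 on the log2(FPKM + 1) scale (SE 0.0465, adjusted p = 4.99e-07). MDM2, which encodes a ubiquitin ligase, fell from 4.25 ± 0.55 to 2.33 ± 0.0461 FPKM (SD, n = 3 per group; limma, log2 change -0.65, adjusted p = 0.000238). HOXC8, a homeobox transcription factor, stood at 1.11 ± 0.133 FPKM in controls and 0.527 ± 0.069 FPKM after knockdown (SD, n = 3), with all 3 knockdown libraries below all 3 controls. Its mean of 0.82 FPKM lay under the 1 FPKM needed to enter the test. Without that filter, limma gave HOXC8 a log2 change of -0.47 (SE 0.06, adjusted p = 0.00227). FTO and MDM2 were the 2 measured members of the list of genes the study itself named, and both fell. FTO is the target of the knockdown and MDM2 is named by the study of these samples, so their count is not independent evidence, and the list did not pass camera (adjusted p = 0.113).

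**Figure D1:**
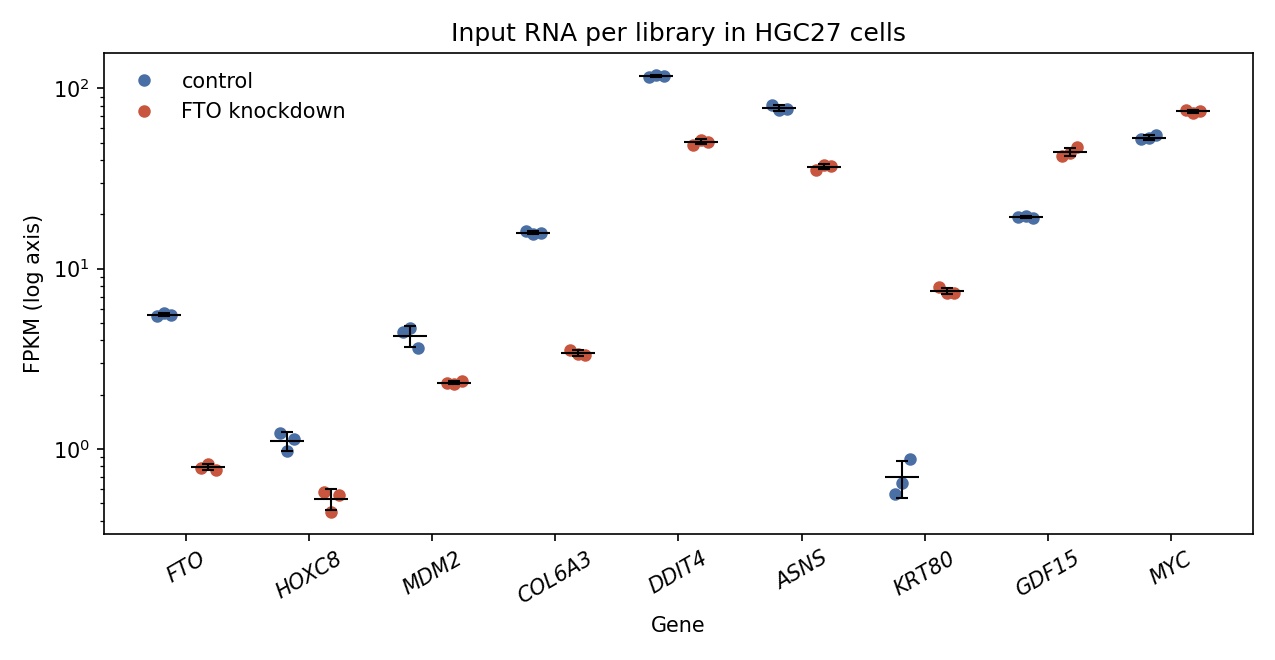
FPKM on a log axis for 9 genes in the 3 control and 3 FTO knockdown input libraries; each point is a library, and bars give the mean and SD. FTO, HOXC8, MDM2, COL6A3, DDIT4 and ASNS lay lower in all knockdown libraries, and KRT80, GDF15 and MYC lay higher.

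Structural, metabolic and secreted proteins were among the genes that moved most. COL6A3, a chain of collagen VI, fell from 15.9 ± 0.287 to 3.41 ± 0.12 FPKM (SD, n = 3), which limma put at -1.94 on the log2 scale (SE 0.0415, adjusted p = 3.10e-07). The epithelial keratin gene KRT80 rose from 0.698 ± 0.164 to 7.52 ± 0.325 FPKM (SD, n = 3; limma, log2 change 2.33, adjusted p = 1.23e-06). GDF15, a stress-induced secreted factor, rose from 19.3 ± 0.314 to 44.4 ± 2.46 FPKM (SD, n = 3). Other falls of the same rank were those of SUMF2, H6PD, PCK2, NRN1, TMEM123, HSPA13, ALDH3A1 and DEPTOR, each between 2.61-fold and 2.96-fold lower. PCK2 is the mitochondrial phosphoenolpyruvate carboxykinase, H6PD makes NADPH in the endoplasmic reticulum, and DEPTOR binds and inhibits mTOR. PRKAR1B, a regulatory subunit of protein kinase A, rose 3.13-fold. ANKRD52, a subunit of protein phosphatase 6, rose 2.41-fold and the integrin gene ITGA3 rose 2.26-fold. AC090192 rose from 0.356 to 2.48 FPKM. KRT81 rose from 0.323 to 3.90 FPKM and POLR2J4 from 3.41 to 8.38 FPKM, but both have near-identical relatives in the genome, so their levels are uncertain.

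Of the 4515 genes with a mean of at least 1 FPKM, 2819 (62.4%) changed in limma at an adjusted p under 0.05, 1107 up and 1712 down. Most changes were small: the median absolute log2 change of the called genes was 0.326, and 9 genes rose and 30 fell by at least 1 on the log2 scale. Values of the groups did not overlap in 67.8% of the tested genes, where chance gives 10%. The first principal component held 73.1% of the variance and separated the conditions. The balance of directions depended on the scaling between libraries. Of the called genes 39.3% rose as deposited, 52.5% (1425 up, 1291 down) after quantile normalization and 55.4% (1507 up, 1213 down) after median-centring. The share was 51.8% (830 up, 773 down) among genes of at least 5 FPKM and 61.7% (1364 up, 845 down) by the q-values of the authors' deposited table. No statement on whether more genes rose or fell is therefore made, and counts under the other scalings are given below for several lists.

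Of 13 measured cholesterol synthesis genes, 7 rose and none fell. Among those that rose were the transcription factor gene SREBF2 (25.3 ± 1.56 to 31.4 ± 0.7 FPKM), the cyclase gene LSS (13.5 ± 0.542 to 16.7 ± 0.746 FPKM, SD, n = 3), EBP and FDPS. SQLE stood at 105 and 99.7 FPKM and did not pass the test. Camera with a preset correlation of 0.01 called the list (adjusted p = 0.0169 over 23 lists), and the call was lost at adjusted p = 0.535 with an estimated correlation and at adjusted p = 0.11 after quantile normalization, while median-centring gave 0.0225. Of 8 transcripts of the mitochondrial genome, 6 rose and none fell. MT-CYB, which encodes cytochrome b, went from 47.2 ± 5.08 to 95 ± 8.73 FPKM and MT-ND1, a complex I subunit, from 110 ± 7.41 to 171 ± 19 FPKM (SD, n = 3), while MT-ND4 and MT-ND5 did not pass. Camera called this list at adjusted p = 0.0367, but gave adjusted p = 0.679 with an estimated correlation and 0.11 after quantile normalization. Without control library 1 or 2, or knockdown library 1 or 3, its camera adjusted p was 0.0839, 0.0619, 0.0688 and 0.0602. With an estimated correlation 1 list had an unadjusted p under 0.05 in camera and 0 passed after adjustment. Fry, which does not compare a list with other genes, passed further lists, where 62.4% of all tested genes had changed. Its adjusted p was 6.1e-06 for cholesterol synthesis, 0.0391 for mitochondrial transcripts, 7.61e-05 for the unfolded protein response and 3.21e-05 for hypoxia. Lists that did not pass fry included ferroptosis suppressors (adjusted p = 0.0857), HOX genes (0.0642), apoptosis regulators (0.055) and oxidative phosphorylation (0.236).

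Stress-response and hypoxia genes moved both ways, with the larger changes downward. Among 10 measured members of the unfolded protein response and ATF4 list, 7 fell and 2 rose. DDIT4, an inhibitor of mTOR signalling, fell from 117 ± 1.67 to 50.5 ± 1.59 FPKM and ASNS, asparagine synthetase, from 77.7 ± 2.73 to 36.7 ± 1.2 FPKM (SD, n = 3; limma adjusted p = 1.23e-06 and 3.43e-06). The chaperone-related genes PDIA4 (149 to 81.4 FPKM) and HSP90B1, together with SHMT2, CHAC1 and ATF4 itself (146 to 118 FPKM), also fell, whereas SESN2 (19.5 ± 0.191 to 30.6 ± 1.33 FPKM, SD, n = 3) and PPP1R15A rose. Of 7 hypoxia-response genes, 5 fell, among them DDIT4 again, the angiogenic factor gene VEGFA (10.4 to 6.33 FPKM) and LOX, a collagen cross-linking enzyme gene that fell from 18.1 ± 1.0 to 8.98 ± 0.414 FPKM (SD, n = 3). The glucose transporter gene SLC2A1 and ENO1 rose. Neither list passed camera (adjusted p = 0.26 for each).

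Ferroptosis genes moved in both directions. Of 8 measured suppressors, FTH1 (ferritin heavy chain, 590 to 714 FPKM) and SLC3A2, a subunit of the cystine transporter, rose. GSS, which makes glutathione, fell from 8.39 ± 0.617 to 5.93 ± 0.15 FPKM and MBOAT2 from 4.50 ± 0.313 to 3.31 ± 0.168 FPKM (SD, n = 3). CISD1, STARD7, TXNRD1 and DHODH did not pass, and camera gave an adjusted p of 0.981. Of 13 drivers and markers, 5 rose and 3 fell (camera adjusted p = 0.27), with 4 up and 2 down after quantile normalization and 8 up and 1 down after median-centring (camera adjusted p = 0.76 and 0.305). KEAP1, the adaptor that targets NRF2 for degradation, rose from 22.2 ± 1.38 to 34.2 ± 0.717 FPKM, and CHAC1, which degrades glutathione, fell from 31.0 ± 1.73 to 22.0 ± 0.941 FPKM (SD, n = 3). ATG7, BAP1, STEAP3 and SLC38A1 rose, and POR and CARS1 fell.

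Apoptosis regulators of opposite function rose side by side. Among 9 measured, the anti-apoptotic BCL2L1 rose from 20.3 ± 2.26 to 33.2 ± 0.958 FPKM and the pro-apoptotic BAX from 12.5 ± 0.302 to 17 ± 1.17 FPKM (SD, n = 3). BID also rose, and cytochrome c (CYCS) fell from 25.9 ± 1.76 to 17.9 ± 0.618 FPKM (SD, n = 3; camera adjusted p = 0.388).

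Cell cycle lists each held members in both directions. The mitotic kinase gene PLK1 (30.4 ± 2.71 to 48.7 ± 2.34 FPKM) and BIRC5 (22.2 ± 0.625 to 29.5 ± 1.72 FPKM, SD, n = 3) were among 4 of 9 G2/M genes that rose, and TOP2A, BUB1 and CKAP2 fell (camera adjusted p = 0.26). After quantile normalization 3 G2/M genes were up and 3 down, and after median-centring 6 were up and 2 down. Of 10 genes of G1/S and replication, 5 rose, including UHRF1 (14.6 ± 1.08 to 23.4 ± 0.59 FPKM), GINS2 (8.65 ± 0.351 to 13.0 ± 0.632 FPKM, SD, n = 3) and MCM7, and 3 fell (camera adjusted p = 0.26); median-centring gave 6 up and 2 down. Immediate early genes included MYC, which rose from 53.4 ± 1.53 to 74.5 ± 1.71 FPKM (SD, n = 3), as did DUSP1, KLF6, FOSB, KLF4 and JUN. SPRY4 (6.39 ± 0.0293 to 4.24 ± 0.0991 FPKM, SD, n = 3), EGR1 and FOS fell (6 up and 3 down of 12, camera adjusted p = 0.26). Transcripts tied to FTO in published work overlapped with these lists in MYC and UHRF1; ATG7 and MZF1 rose and CXCR4 fell, 4 up and 1 down of 7 (camera adjusted p = 0.113).

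Among 12 measured genes of the m6A machinery, 6 fell and 1 rose (camera adjusted p = 0.475); after median-centring 3 fell and 2 rose. The falls beside FTO were those of the reader HNRNPC (67.3 ± 2.06 to 55.4 ± 3.48 FPKM, SD, n = 3), the methyltransferase METTL16, the writer-complex member ZC3H13 (4.22 to 2.72 FPKM), the demethylase ALKBH5 and IGF2BP3, and RBM15B rose. In the HOX clusters, 2 of 14 measured genes rose and 5 fell (camera adjusted p = 0.952), but quantile normalization turned this to 6 up and 3 down and median-centring to 3 up and 2 down. HOXB7 rose from 3.80 ± 0.12 to 5.35 ± 0.427 FPKM and HOXC13 fell from 9.53 ± 0.556 to 7.31 ± 0.263 FPKM (SD, n = 3).

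Few members of the remaining lists were measured, and no remaining list passed camera. Of 4 interferon-stimulated genes, IRF1 (2.62 ± 0.12 to 3.84 ± 0.09 FPKM) rose, and STAT2 (12.2 ± 0.6 to 8.24 ± 0.0532 FPKM, SD, n = 3) and DDX58 fell (adjusted p = 0.865). NF-kB targets went 2 up (LIF and RELB) and 2 down (SOD2, 1.81 to 1.16 FPKM, and TNFAIP3, 1.58 to 1.20 FPKM; adjusted p = 0.981), though TNFAIP3 lost its call after quantile normalization or median-centring. Of 4 ribosomal protein genes, RPS18 (169 to 145 FPKM), RPS27A (29.4 to 21.6 FPKM) and RPS14 fell (adjusted p = 0.475), and after median-centring 1 of the 4 fell, RPS27A. The oxidative phosphorylation list had 6 measured genes (adjusted p = 0.981) and no direction common to the scalings, and COX5B stood at 75 and 68.6 FPKM without passing. Among 3 epithelial-mesenchymal genes, LOX fell and TGFB2 stood at 4.97 and 5.65 FPKM (adjusted p = 0.865); quantile normalization and median-centring each gave 1 up and 1 down. The only histone gene measured, H2BC21, rose from 21.4 to 33.8 FPKM (adjusted p = 0.26). For markers of other cell types, the gastric epithelial MUC1 stood at 1.24 and 1.43 FPKM (adjusted p = 0.722) and passed as a rise after quantile normalization or median-centring. The fibroblast markers COL1A1 and THY1 moved apart (169 to 147 and 12.5 to 15 FPKM; adjusted p = 0.868), with COL1A1 losing its call after median-centring. No immune marker was measured. Adjusted over the list alone, 4 G1/S genes fell, and the other counts given above stayed the same. For the HOX and NF-kB lists the means of -0.028 and -0.0216 went against an upward median and camera direction.

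The m6A maps of both conditions had peaks on MYC, NEAT1, MALAT1 and FTO. The fold enrichment of IP over input given with each peak is the authors' own value and is used to describe and rank peaks within a list. On MYC, the peak of highest enrichment in the control list lay in the 3' UTR on chromosome 8 from 127740645 to 127741453 (36.0-fold), and that of the knockdown list from 127740674 to 127741304 (20.1-fold). The non-coding RNA NEAT1 had its highest peak on chromosome 11 at 65423517 to 65425285 in controls (82.6-fold) and at 65424928 to 65425047 after knockdown (117-fold). MALAT1, from the same region of chromosome 11, had its highest peak at 65499035 to 65501010 in controls (9.41-fold) and at 65499364 to 65500770 after knockdown (6.60-fold). On FTO the highest control peak lay in the 3' UTR at 54121543 to 54121663 of chromosome 16 (9.16-fold) and the highest knockdown peak in an exon at 53825926 to 53844219 (11.3-fold). That control peak was weak by the authors' peak call (log10 p of -2.16), unlike the knockdown peak (-228). The control list also had enrichment at the differential exon peak of FTO (4.22-fold), so the highest peaks do not show a shift between sites. The controls had 39492 peaks in 18324 genes with a median enrichment of 6.11 (quartiles 3.05 and 10.2), and the knockdown had 28888 peaks in 14170 genes with a median of 7.05 (quartiles 3.83 and 12.7). Peaks covered a median of 330 exonic bp in controls and 271 bp after knockdown. The lists were called per condition, without replicates, so their lengths were not tested; the ratio of 1.37 control to knockdown peaks was 1.21 among peaks of at least 4-fold enrichment and 1.04 at an adjusted p of at most 1e-05.

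Both lists had a peak on 13214 genes, whether or not the peaks overlapped, with 5110 genes having a peak in the control list alone and 956 in the knockdown list alone. Of the control peaks 57.9% (95% exact binomial interval 57.4% to 58.4%) overlapped a knockdown peak by at least 1 bp, and of the knockdown peaks 88.8% (88.5% to 89.2%) overlapped a control peak. With 50% reciprocal overlap the shares were 35.1% and 57.1%, so they depend on the rule far more than the intervals show. The intervals cover counting error only. Peaks outside the overlap were the weaker ones of each list, with a median enrichment of 4.28 against 7.27 for shared control peaks and of 3.72 against 7.51 for shared knockdown peaks. The position along transcripts was similar: 47.6% of control peaks (47.1% to 48.1%) and 46.5% of knockdown peaks (45.9% to 47.0%) lay in 3' UTRs. The 5' UTRs held 12.6% (12.3% to 13.0%) and 13.9% (13.5% to 14.3%), and other exons 39.8% and 39.6%. By transcript type, 33.4% of control and 36.4% of knockdown peaks were listed as protein-coding, and 17.4% and 14.7% as long non-coding RNA. Other listed types included retained introns, processed transcripts, transcripts subject to nonsense-mediated decay and processed pseudogenes. The type is that of a transcript and not of its gene, so these are not shares of peaks on protein-coding genes.

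HOXC8 had a differential peak that was listed as higher after FTO knockdown. This peak on chromosome 12, from 54011158 to 54011457 in the 3' UTR, rose by 1.18 on the log2 scale (2.27-fold, adjusted p = 2.75e-03 in the authors' deposited table). HOXC8 had a mean of 0.82 FPKM, under the 1 FPKM asked of tested genes. Its input RNA fell from 1.11 to 0.527 FPKM, so the ratio over input rests on low values. FTO itself had a differential peak in an exon on chromosome 16, from 53814822 to 53844219, that rose by 0.71 (adjusted p = 7.94e-23 in the authors' deposited table). The peak named for MDM2 on chromosome 12, from 68842197 to 68851341, fell by 0.82 in the authors' deposited table (adjusted p = 7.24e-03). That span runs past the 3' end of MDM2 into CPM, a neighbouring gene, and the listed peak with the same start and end was called on CPM. The 3' end peak that was both named for MDM2 and called on its model had an enrichment of 21.3 in the control list and 25.8 in the knockdown list. No peak called on MDM2 had the start and end of the differential peak.

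**Figure D2:**
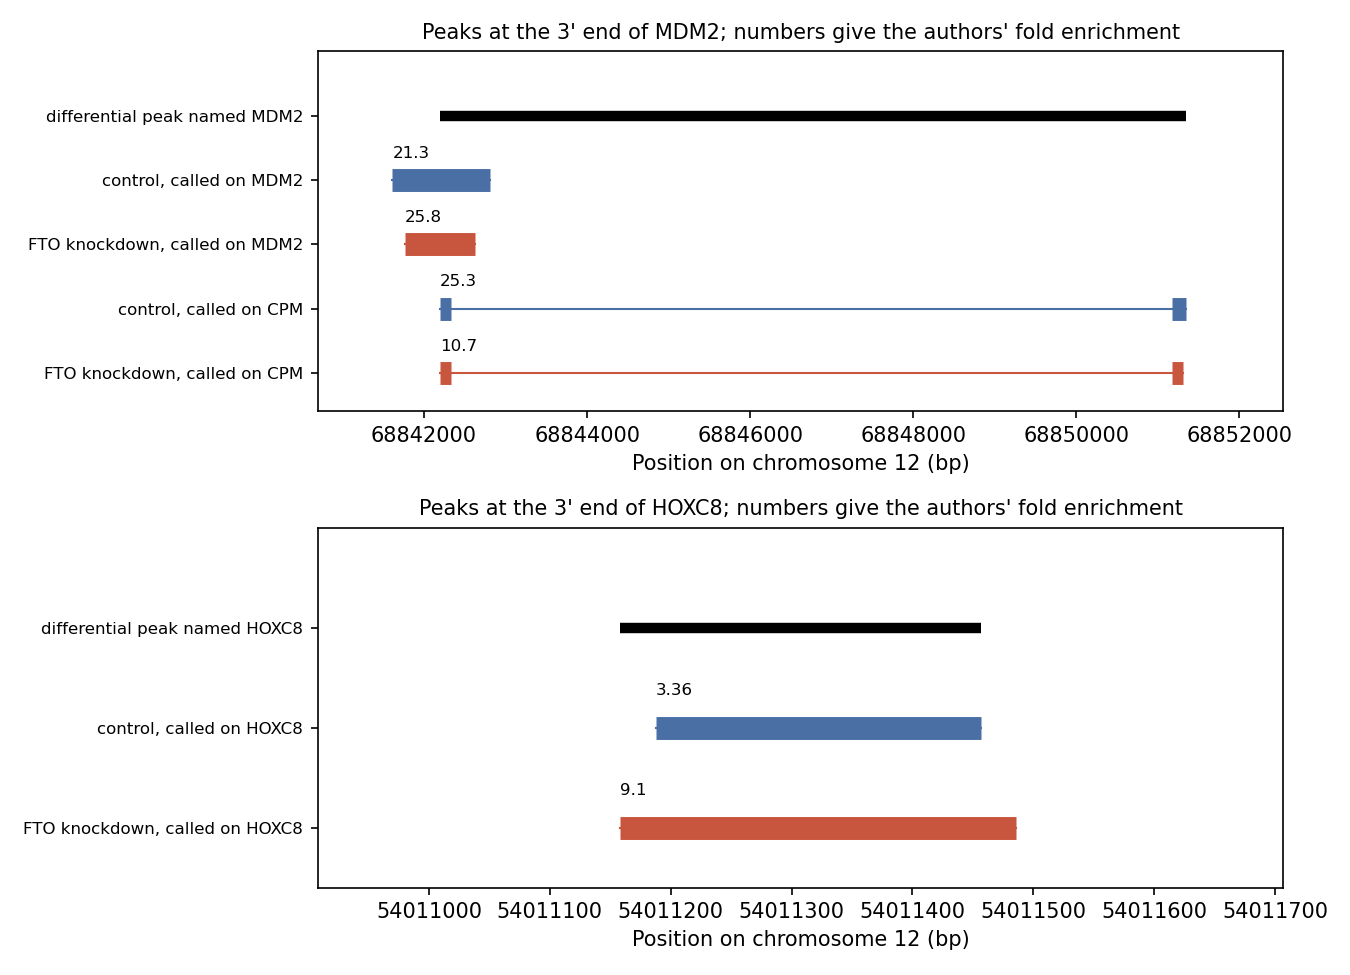
Peaks called on MDM2, CPM and HOXC8 along chromosome 12 (position in bp) at the 3' ends of MDM2 and HOXC8; blue and red bars are exonic blocks of control and knockdown peaks with the authors' fold enrichment, black bars are differential peaks, and thin lines join blocks. The differential peak named for MDM2 spans the blocks called on CPM, and that of HOXC8 lies on the peaks called on HOXC8.

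More differential peaks rose than fell in the authors' deposited table, whose scaling between IP libraries was not known. Of the 8687 peaks with a gene name in the authors' deposited table, 4811 rose and 3876 fell after knockdown, so that 55.4% rose (95% exact binomial interval 54.3% to 56.4%, counting error only). The median absolute log2 change was 0.691. In 5' UTRs 65.5% of 1251 differential peaks rose (62.8% to 68.1%), against 53.4% of 4723 in 3' UTRs and 54.2% of 2713 in other exons. The odds of a rise were 1.66 times higher in 5' UTRs than in 3' UTRs (Fisher's exact test, two-sided, p = 1.32e-14, over peaks, which are not independent replicates). Among peaks with an absolute log2 change of at least 1, 63.4% of 2299 rose, and 67.5% of 1925 when an adjusted p under 0.05 was required as well. Higher listed enrichment after knockdown was also more frequent over all paired peaks. Of 18533 peaks that overlapped 1 to 1 on the same gene model, 59.6% were higher in the knockdown list (63.8% in 5' UTRs, 57.9% in 3' UTRs). The balance of directions and the higher share in 5' UTRs were thus also seen over all pairs. Differential peaks were not removed from these pairs, so whether either pattern holds outside them was not tested. Values of single IP libraries were not used, so the spread between replicates behind the differential peaks is not known here.

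Among genes of at least 1 FPKM, with 1 peak per gene, many of the largest changes named genes with near-identical copies elsewhere in the genome, whose reads cannot be assigned with certainty. In the authors' deposited table, BOLA2B rose by 6.59 on the log2 scale (chromosome 16, 30192932 to 30193229, 3' UTR), followed by RGPD1 (4.78), TUBB2BP1 (4.58), CXorf49B (4.13), NOMO3 (4.06), NOMO2 (3.87) and PI4KAP2 (3.49). Also in the authors' deposited table, ARID1B, a subunit of chromatin remodelling complexes, rose by 3.87 in its 3' UTR (chromosome 6, 157071309 to 157071519), HMGXB3 by 3.58, and a peak named for NSMF but called on its neighbour PNPLA7 by 3.64. The deepest falls among these genes in the authors' deposited table were those of CBWD3 (-5.41), ZNF155 (-5.18, called on ZNF221), GOLGA2P7 (-5.17), EIF3C (-4.71) and ZNF322P1 (-4.42), again members of duplicated families. FP565260 (-3.51), DCAF7 (-3.46, 3' UTR on chromosome 17), AC126696 (-3.44), SOS2 (-3.32) and PRICKLE3 (-3.28, called on SYP) followed in the authors' deposited table. In it HMGXB3, PI4KAP2, GOLGA2P7, SOS2 and PRICKLE3 had adjusted p-values of 6.31e-02, 7.41e-02, 9.12e-02, 5.13e-02 and 9.77e-02.

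Every differential peak on the mitochondrial genome fell. There were 14 such peaks, named for 11 genes, with log2 changes from -0.704 to -1.17 in the authors' deposited table; the deepest was in MT-ND2 (4470 to 5511) and MT-ND1 fell by 0.87. The control list held 15 mitochondrial peaks and the knockdown list 0. Of the mitochondrial list members with a peak, 8 of 11 (72.7%) had a peak that fell, against 17% of all genes with a peak (Fisher's exact test, adjusted p = 0.00341 over 48 tests). RNA of 6 of these transcripts rose in the input libraries, as given above. HOX genes also had a falling peak more often than other genes: 15 of 36 (41.7%) had a peak that fell (Fisher's exact test, adjusted p = 0.0104), while 6 (16.7%) had a peak that rose. HOXA13 (-0.62, called on the antisense RNA HOTTIP), HOXA11 (-0.53, called on HOXA11 and HOXA11-AS), HOXA4 (-1.22) and HOXD8 (-0.93) fell in the authors' deposited table, while HOXC8, HOXA9 and HOXD9 rose. HOX peaks can overlap neighbouring and antisense genes, so the gene named for a peak is uncertain. The other 46 tests did not pass. Against genes of at least 1 FPKM, 3 tests passed (Fisher's exact test): HOX genes with a falling peak (13 of 14, adjusted p = 0.0156), and mitochondrial transcripts with a falling (8 of 8, adjusted p = 0.0446) and with fewer rising peaks (0 of 8, adjusted p = 0.0156). FPKM were listed only for genes with a differential peak, so every gene of this background had a rising or a falling peak. For mitochondrial transcripts, 8 of 8 falling thus follows from 0 of 8 rising, and both tests state the same fact. When only peaks with an absolute log2 change of at least 1 were counted, 0 of the 48 tests passed and 0 had an unadjusted p under 0.05 in Fisher's exact test. The tests count genes, which are not independent replicates.

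Genes of the m6A machinery had a rising peak in 10 of 23 members (43.5%, against 18.8% of all genes; Fisher's exact test, adjusted p = 0.091) and a falling peak in 6 (26.1%, against 17%; adjusted p = 0.665). Against genes of at least 1 FPKM, all of them with a differential peak, 10 of 12 had a rising peak (Fisher's exact test, adjusted p = 0.941). IGF2BP3, a reader protein gene, had a peak that rose by 1.89 in an exon on chromosome 7 and a pair of peaks that fell (-0.64 and -0.32) in the authors' deposited table. HNRNPC rose by 0.35 in its 3' UTR in the authors' deposited table. Ferroptosis drivers had a rising peak in 10 of 27 members and a falling peak in 7 (Fisher's exact test, adjusted p = 0.256 and 0.664), with HMGB1 (1.13, 3' UTR) and BAP1 (0.93) leading by p in the authors' deposited table. For ferroptosis suppressors 4 of 22 had a rising and 4 a falling peak (Fisher's exact test, adjusted p = 1.0 for both); FTH1 rose by 0.56 and STARD7 fell by 0.45 in the authors' deposited table. BAX rose by 1.16 in its 3' UTR in the authors' deposited table. Stress and hypoxia transcripts whose RNA fell had peaks in both directions in the authors' deposited table: DDIT4 rose (0.63), ASNS (-0.55) and SHMT2 (-0.59) fell, and VEGFA (0.25 and -0.70) and HSP90B1 (0.71 and -0.61) did both. Peaks of PPP1R15A (0.72), JUN (0.74) and FOS (0.47) rose in the authors' deposited table, where IRF1 had a peak that rose by 1.35 and another that fell by 2.74. SQLE fell by 0.47 in the authors' deposited table, and EBP had a rising (0.83) and a falling peak (-0.49). A peak in the 5' UTR of MYC fell by 0.21 and one named for MZF1 rose by 0.38 in the authors' deposited table.

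Further members, each given by its peak of smallest p, were spread over both directions. In the authors' deposited table rises were listed for FEN1 (0.42), MCM7 (0.93), BCL2L1 (0.68, called on ABALON), COL5A1 (2.13, an exon on chromosome 9 from 134785033 to 134789187), STAT2 (0.39), TNFAIP3 (0.90), LIF (0.75), RPL8 (1.29, 5' UTR), H2BC21 (1.44) and THY1 (1.39). The authors' deposited table listed falls for AURKA (-0.45), TOP2A (-0.62), TGFB2 (-0.45), SDHD (-0.34, called on NKAPD1), RPS18 (-0.53), MUC1 (-1.01) and COL1A1 (-0.50). None of their lists passed the test for rising or for falling peaks, with the oxidative phosphorylation list closest, 5 of 11 members having a falling and 2 a rising peak (Fisher's exact test, adjusted p = 0.256 and 1.0).

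Changes in m6A and in RNA level had a weak positive relation across genes. Over 4515 genes, Spearman's rho between the largest peak change of a gene in the authors' deposited table and its input log2 change was 0.187 (permutation p = 1e-05, the smallest that 100000 permutations can give). Of the 2819 called genes, 46.7% rose where the peak rose and 29.3% rose where the peak fell (Fisher's exact test, two-sided, odds ratio 2.11, p = 6.34e-21). BAX, FEN1 and MCM7 gained both m6A and RNA, and STAT2, DDIT4 and FTO gained m6A with less RNA. The relation was across genes, which are not independent replicates. It was weaker in the upper 3 quintiles by expression, with rho at 0.271, 0.253, 0.0863, 0.0791 and 0.12 from the lowest to the highest, and at 0.0892 over 2390 genes of at least 5 FPKM (permutation p = 1e-05, again the smallest possible).

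**Figure D3:**
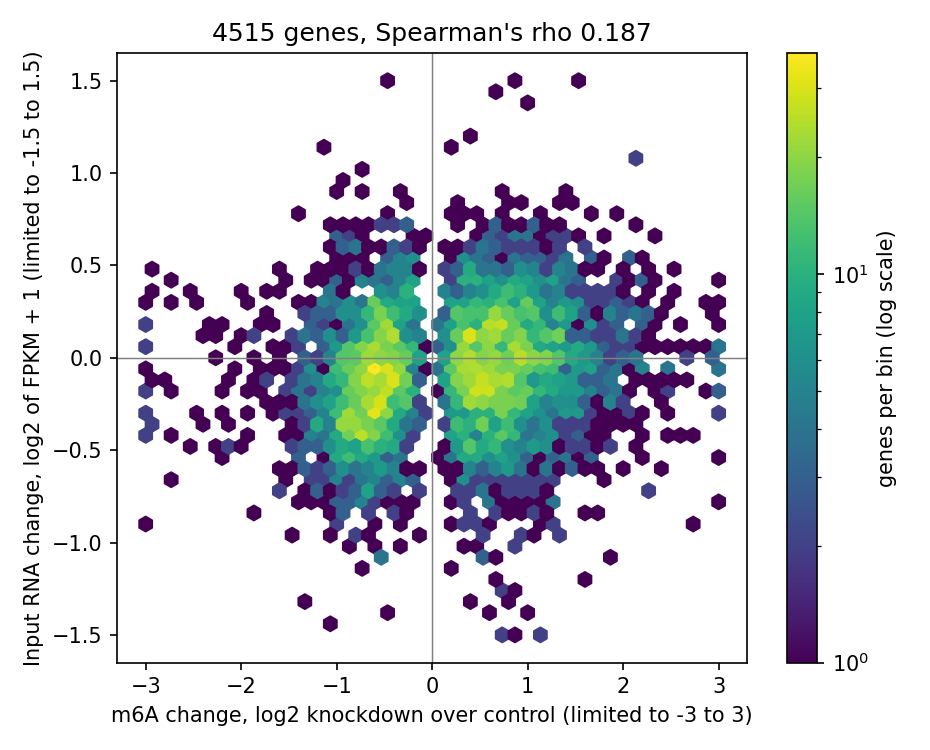
Change in m6A (x axis, log2 knockdown over control in the authors' deposited table, limited to -3 and 3) against change in input RNA (y axis, log2 of FPKM + 1, limited to -1.5 and 1.5) for 4515 genes; colour gives genes per bin on a log scale. Points lie in all 4 quadrants, with a rho of 0.187.

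Direction of m6A change followed the gene content of the genomic neighbourhood, a comparison added after the data were seen. Of differential peaks in the authors' deposited table with 0 to 7 protein-coding genes within 500 kb either side, 39.8% rose (37.6% to 41.9%), against 73.8% (71.6% to 75.9%) of peaks with 30 to 75 such genes. Chromosomes 16 and 19 had the largest shares of rising peaks, 71.7% and 71.4%, and chromosomes 4 and 18 the smallest, 37.8% and 38.1%. Over 4504 genes rho between m6A change and the number of neighbouring genes was 0.282 (95% bootstrap interval 0.255 to 0.31) and 0.212 (0.184 to 0.241) within chromosomes. The change in input RNA followed it too, with a rho of 0.251 (0.224 to 0.277).

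**Figure D4:**
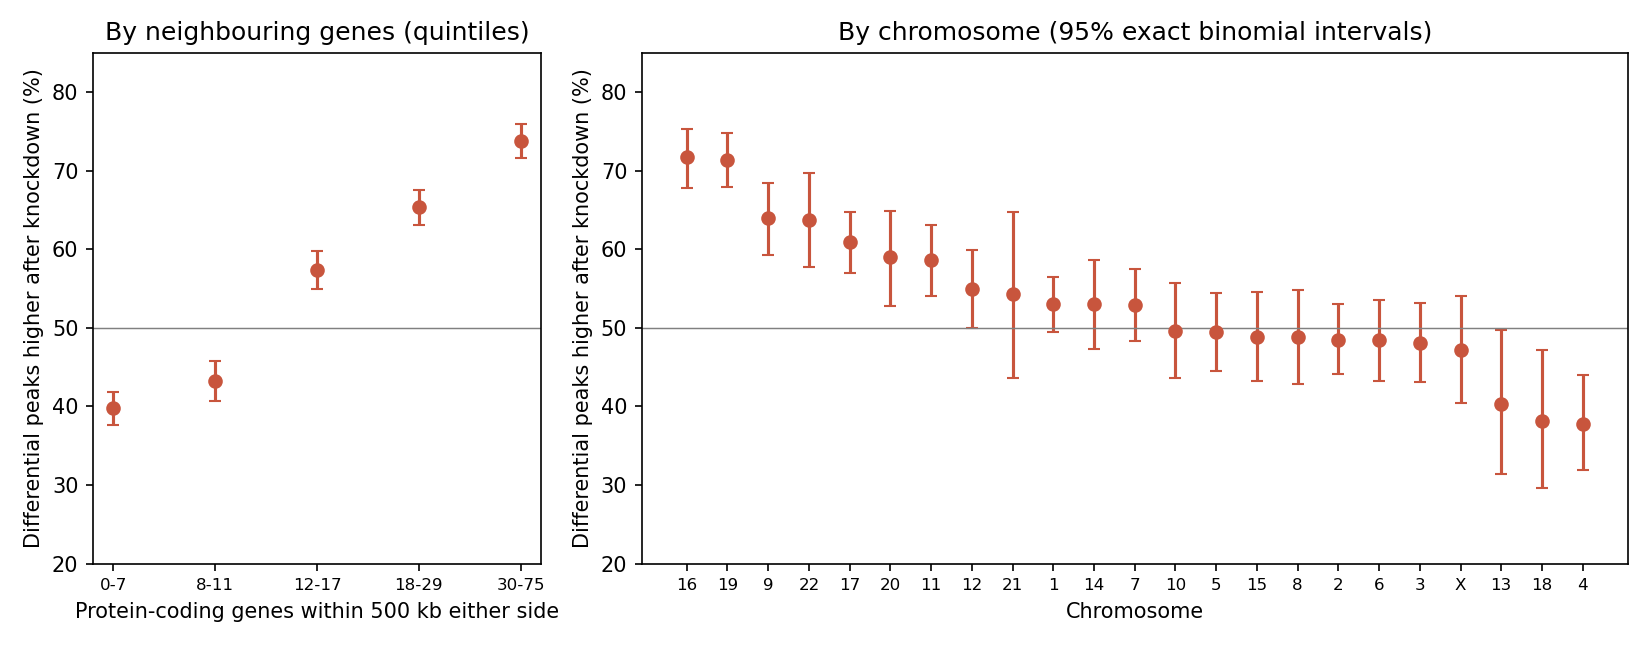
Share of differential peaks that rose after knockdown (y axis, percent) by quintile of the number of protein-coding genes within 500 kb (left) and by chromosome (right); bars are 95% exact binomial intervals, and the grey line marks equal shares. The share climbs from 39.8% to 73.8% over the quintiles.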

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

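The tests in this part were chosen after the result was seen. Among the differential peaks, 283 had no gene name and lie outside the comparisons of the report; they drew attention because they carry a signal that the report does not use. In all 283 the field for the p-value held a number above 1. According to the authors' deposited table, 134 of them rose and 149 fell after knockdown, over 238 gene identifiers, 0 of which had FPKM values. Their deposited log2 value had a rho of -0.821 with the knockdown over control ratio of listed enrichment over 129 peaks, close to the -0.813 of the named peaks, so the direction of the field was the same. Counting them gave 8970 differential peaks, of which 55.1% rose. No biological explanation was tested.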

How the results depend on the processing

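The settings with the neighbouring-gene trend removed, median-centred lists, peaks without a gene name, overlapping peaks counted once, and the joint threshold on adjusted p and size were chosen after the data were seen. Of 55 named genes, 46 kept their direction and side of the threshold under every setting other than a size threshold, 9 changed side (among them TGFB2, MUC1, COX5B, RPS18, TNFAIP3 and COL1A1, and by the authors' q-values alone HOXC13 and HNRNPC) and 0 reversed. Called genes numbered 2819 and were 2823 and 2822 under pseudocounts of 0.1 and 0.01, with 3075 under no filter, 2716 after quantile normalization, 2720 after median-centring and 2818 in limma without a trend. Removing the trend gave 2809, of which 2470 were shared. A filter of 5 FPKM gave 1603 (773 fell), with fewer genes tested. The authors' q-values gave 845 that fell; the cause was not tested. A size threshold of 1 on the log2 scale left 39 genes, 9 up and 30 down, by its construction. Leaving out a library gave 2413 to 3005 called genes, 941 to 1173 up and 1441 to 1832 down.

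Pairing of the samples by library number was not seen: deviations of equally numbered libraries correlated at -0.0769, 0.0278 and 0.0247. Those of unequally numbered libraries ran from -0.176 to 0.189. So few libraries cannot exclude shared handling, and no library pair was treated as matched. With the number as a replicate block, 2747 genes were called, and 2 lists passed. Gene lists past camera numbered 2; they were 4 without the filter, 0 after quantile normalization, 0 with an estimated correlation, 1 after median-centring and 1 to 2 with a library left out. The cause was not tested.

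Control peaks numbered 25679 at an enrichment of at least 4 and 24373 at an adjusted p of at most 1e-05, by construction. Shared control and knockdown peaks were 35.1% and 57.1% with 50% reciprocal overlap, 61.3% and 84.1% at an enrichment of at least 4, and 72.9% and 83.4% with lists of equal length. The 3' UTR share was 46.6% of control peaks at an enrichment of at least 4, and 48.3% of control and 47.8% of knockdown peaks with 1 peak per gene. Differential peaks fell to 2299 (1457 up, 842 down) with a size threshold of 1 and to 1925 (1300 up, 625 down) with both thresholds, by construction. The share that rose was 57.2% at an adjusted p under 0.05, 63.4% and 67.5% under the size and the joint threshold, 53.3% with 1 peak per gene and 59.4% in genes of at least 1 FPKM; it stayed above 50% in all of these, and the cause of the moves was not tested. List tests among peaks passed in 0 cases with the size threshold, where fewer peaks remained. Alternatives for the motif and for the IP libraries were not run. Depth was unknown, and its effect on weak peaks was not tested.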

Other observations

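The tests in this part were chosen after the result was seen, apart from the count of sample splits for the gene lists. Extracellular matrix genes fell more often than other tested genes. Of 44 tested genes of this Gene Ontology term, 34 fell and 2 rose (Fisher's exact test against 4515 tested genes, odds ratio 5.66, adjusted p = 0.000165 over 1316 terms), and 33 fell after quantile normalization and 31 after median-centring. Beside COL6A3 and LOX, the matrix protein gene CCDC80 went from 9.22 ± 0.705 to 4.05 ± 0.22 FPKM and VASN, a TGF-beta binding protein gene, from 22.9 ± 0.0942 to 13.6 ± 0.388 FPKM (SD, n = 3). FLRT1 went from 6.83 to 3.48 FPKM. Among genes of matrix organization 31 of 45 fell and 8 rose, the integrin gene ITGA3 and the collagen receptor gene DDR1 among the risers (Fisher's exact test, adjusted p = 0.0185). Only genes with a differential m6A peak entered these expression counts, and no explanation was tested for them. Fisher's exact test treats genes as independent, here and for the terms below. Camera with an estimated correlation between genes, which passed 0 of the gene lists, was not applied to these terms.

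Genes of ribosome biogenesis and of methyl-CpG binding rose more often than other tested genes. Of 43 ribosome biogenesis genes 25 rose and 8 fell (Fisher's exact test, odds ratio 4.35, adjusted p = 0.00117), with the nucleolar protein gene NOP56 going from 25.2 ± 1.43 to 40.3 ± 1.1 FPKM and the helicase gene DHX37 from 5.60 ± 0.574 to 10.9 ± 0.714 FPKM (SD, n = 3). RPS28, a protein of the small ribosomal subunit, went the other way, from 46.6 to 28.1 FPKM. Of 10 genes annotated to methyl-CpG binding 9 rose (Fisher's exact test, adjusted p = 0.00459): TET3, an oxidase of 5-methylcytosine, went from 7.93 ± 0.341 to 15.6 ± 0.523 FPKM, and UHRF1, PRMT5, DNMT1 and MBD3 rose too. Heterochromatin genes rose in 13 of 20 cases with 0 falls (Fisher's exact test, adjusted p = 0.0145), among them CBX5, HDAC1 and SUV39H1. Rises outnumbered falls in these terms after quantile normalization, median-centring and removal of the trend with neighbouring genes. Over all called genes they also did so after quantile normalization (1425 and 1291) and median-centring (1507 and 1213), but not after removal of the trend (1105 and 1704). Enrichment of these terms was not tested again under those scalings. Among transcripts, chromatin binding genes had a rising m6A peak in 134 of 384 cases (34.9% against 18.8% of genes; Fisher's exact test, adjusted p = 1.71e-10), and 89 had a falling one. Genes of the mitochondrial inner membrane had a falling peak in 86 of 307 (28.0% against 17%; Fisher's exact test, adjusted p = 0.0026). A differential peak of either direction was listed for 194 of the 384 and 132 of the 307 genes, against 6396 of 19340 genes. Both tests thus also count whether a gene had any differential peak, not its direction alone. Neither passed among genes with a differential peak, a smaller background, where the odds ratios were 1.72 for chromatin binding (2.36 before) and 1.78 for the inner membrane (1.92 before; Fisher's exact test, adjusted p = 0.0628 and 0.368), so the loss does not show that the pattern is absent. In that background 205 rising terms became 3 and 5 falling terms became 0. There, inner membrane genes had a rising peak less often, in 50 of 132 cases (37.9% against 56.9%; Fisher's exact test, adjusted p = 0.0163). In the wider background 11942 of 19340 genes carried an annotation, and the others counted as outside every term.

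The change of m6A followed the number of neighbouring genes. Given the change in expression, the partial rho was 0.246 (95% bootstrap interval 0.219 to 0.274), and given the expression level 0.26 (0.232 to 0.287). Adjusting for either as measured did not remove the relation, but imperfect measures cannot exclude them as its cause. The input libraries themselves differed in this trend: slopes ran from -0.0452 to 0.0023 log2 per 10 genes in controls and from 0.0134 to 0.0391 after knockdown. The spread within the controls, 0.0475, came near the difference of 0.0568 between groups, so coverage of single libraries may account for the trend in expression. For m6A, whose slope was 0.191 log2 per 10 genes, a coverage trend of single IP libraries and an effect of the knockdown cannot be told apart, because no values of IP libraries were used.

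The weak positive relation between m6A change and RNA change may reflect more than shared measurements. Error shared through the input libraries would push the covariance below 0 (-0.00764 expected), yet it was 0.0512 (0.0413 to 0.0606). Its sign restates the positive rho given above and is not a separate check. Error of this kind pushes the other way, so it alone does not account for the relation. Given the number of neighbouring genes, the partial rho was 0.131 (0.101 to 0.161). That number is an imperfect measure of the shared trend, so the trend cannot be excluded as the cause. The authors' selection of genes with a differential peak stays open, as does an effect of the knockdown, which was not tested apart from it.

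The differential peak named for MDM2 may be a peak called on the overlapping gene CPM: 1 listed peak had the same start and end on the CPM model, and 0 on the MDM2 model. Of 2284 differential peaks whose start and end matched a listed peak, 541 (23.7%) were called on another gene than the named one. A change of m6A on MDM2 itself was not separately tested.

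With 3 against 3 libraries, 10 splits of the samples exist, too few for a share under 0.05. The real split called 2819 genes, as 1 of 10 splits did, and the highest other called 1. For gene lists 2 of 10 splits reached the real count of 2, and the highest other gave 2.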
